A study of Danio rerio with 4 samples.

How the data were processed

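Single-cell RNA sequencing was performed on zebrafish embryos carrying TgBAC(neurod1:EGFP)nl1, a transgene that labels neurons and endocrine cells expressing the transcription factor neurod1. Cells were dissociated and sorted for GFP and RFP, and libraries were made with the 10x Genomics single cell 3′ version 3 kit, per the labels' protocols. The source of the RFP signal is not given in the sources used here. There were 4 libraries, 1 for each age of 14, 18, 22 and 48 hours post fertilization. The extract protocol of the 18 h library names another age, whereas its library name and the series design give 18 h, which was used. That library also has another prefix in its library name, per the labels, so its age and its batch cannot be separated.

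The authors deposited UMI counts per gene and barcode, whole numbers that show no normalization. The submitters' processing notes name Cell Ranger 3.1.0, and the file header of the 18 h library names another Cell Ranger release. The genome build is not given in the sources used here. The tables of 14, 22 and 48 h hold 36351 genes and that of 18 h holds 32520. The 18 h table uses other gene identifiers, with 0 shared with the other libraries, so genes were joined by symbol, and 26930 symbols were shared. This replaced a join by identifier planned before the data were examined. The listed names isl1a, isl1b, eng1b and tlx3a were read under the synonyms used in the tables.

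Barcodes with at least 500 genes were kept, which left 3175, 11742, 2510 and 4146 cells at 14, 18, 22 and 48 h. Doublets were scored with Scrublet as run in scanpy 1.11.5. Its automatic threshold called 1, 2626, 2 and 1 cells at these ages, so it was not used. Instead, scores above the quantile expected from 0.8% doublets per 1000 barcodes were removed, a choice made after this was seen. It removed 95, 1039, 61 and 185 cells, or 2.99%, 8.85%, 2.43% and 4.46%. The analysed cells held a median of 9459.5 UMIs at 14 h, 12660 at 18 h, 8765 at 22 h and 5694 at 48 h.

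Each library was clustered alone (2000 variable genes, 40 principal components, 15 neighbours, Leiden modularity clustering at resolution 1 on a shared-neighbour graph with igraph 0.11.9). The genes of 4 lists (retinoic acid, Ret and neurotrophins, axon guidance, FGF) were left out. Clusters were named from 28 marker lists fixed before the data were examined. A name needed at least 3 markers raised 1.5-fold in at least 5% of the cells, with 20 CPM added to both sides. A cluster stayed unnamed when its leading genes went against the name, held more markers of another class, or when its UMI count was low. After the data were seen, the lateral-line-like name was made to require hmx2 or hmx3a. Leading genes, among them nkx2.2a, pax6b and nkx6.1, were then also set against erythroid or epibranchial names.

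For tests, counts were summed per library and arm and compared with edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr, library as a block, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. DESeq2 1.42.0 was an alternative. The arms need at least 10 cells each. The ret contrast used pooled sensory-like clusters because fewer than 3 libraries held lateral-line-like cells. The plan fixed beforehand named cranial clusters, but the trigeminal or Rohon-Beard-like class was not divided, so the pool holds trunk neurons too. The p-values rest on 4 libraries that differ in age, and both arms of a library come from the same sorted cells. Standard errors were computed from the F statistic.

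Ages have 1 library each and were compared without a test. CPM carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. A count of 0 was given a floor of 3 counts in ratios. Genes needed a summed count of at least 20. List medians had 0.5 counts added and were placed among 10000 random lists matched on mean expression. With genes of 0 counts set to their bound, the medians given for these libraries' sensory-like cells moved by 0. To compare shares of cells with a ret UMI, cells were thinned to 2000 UMIs and shallower cells were left out.

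The named genes followed a rule fixed beforehand. For the ret contrast it took up to 12 called genes per direction that moved the same way in every library, called list genes and all testable retinoic acid genes, without clone or locus names (identifiers starting with XLOC were read as such). For ages it took the 10 genes per direction whose ratio interval lay farthest from 1 with a count of at least 50, and the 2 highest and lowest members of each list. Mitochondrial, ribosomal, erythroid, epidermal, muscle and hatching gland genes were set apart. Some genes that the rule or the lists take are not reported here.

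The tests were tried on simulated counts. The ret contrast had 99 genes changed by a log2 fold change of 2 and 100 by 1, and the contrast of eya2-high clusters 100 of each. With a spread that followed the trend, the ret contrast (11071 genes) recovered 100% and 79% of them and the other (11689 genes) 86% and 31%, and false calls made up 3.78% and 2.5%. With gene-wise spreads it recovered 100% and 81% (11080 genes) and the other 81% and 16% (11683 genes), and false calls made up 13.5% and 17.1%. The ratio intervals covered 95.5% of the simulated ratios over 10881 genes at 22 h against 14 h.

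Alternatives covered the normalization, test, gene filter, library block, each library left out, cluster resolutions 0.6 and 1.6, at least 1000 genes, doublets kept, list genes in the clustering, at least 2 ret UMIs, depth matching (within 0.2 ln UMI, a limit added after seeing the data) and thinning. Look-alike clusters were also added after seeing the data: unnamed clusters that were not of low UMI count and shared at least 5 of their 25 leading genes with a trigeminal or Rohon-Beard-like cluster of 14 h were counted in that class. Chosen after seeing the data were also the automatic doublet threshold, matching by cluster and depth, and the eya2-high clusters. For the last, matching earlier clusters to the 48 h lateral-line-like cluster by whole-profile correlation was tried first. It picked trigeminal-like or shallow clusters, so the cluster with the highest eya2 level was taken instead at 14, 18 and 22 h. At 48 h this rule would take neural progenitor-like cluster 6, and the lateral-line-like cluster ranks 3 by eya2. Also chosen after seeing the data were the Hox medians per library and the source of the acetylcholine genes at 18 h. For the latter, genes of at least 100 CPM in motor neuron-like cells, and at least 20-fold above ret-negative sensory-like cells, each gave the share of motor neuron RNA that their level in ret-positive cells would need. The gene ret, which defines the arms, was left out after its value was seen. An interval clear of the bound, in place of the median alone, was also required only then.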

Results

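The data are 4 single-cell libraries of neurod1 reporter cells sorted from zebrafish embryos, 1 per age, with 35023368 UMIs at 14 h, 196496137 at 18 h, 43476037 at 22 h and 34093610 at 48 h. After filtering, 3080, 10703, 2449 and 3961 cells were analysed. The reporter's gene, neurod1, stood at 1654 CPM over all cells at 14 h, 1889 at 18 h, 4172 at 22 h and 2455 at 48 h. With 1 library per age, no age difference has a replicate check, and age cannot be separated from library.

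The first question was which cell classes the sort held at each age. Placode-like cells, named from markers such as eya1 and six1b, made up 23.5% of the cells at 14 h (95% interval 22.0 to 25), 13.5% at 18 h (12.9 to 14.2) and 4.33% at 22 h (3.56 to 5.21). Trigeminal or Rohon-Beard-like neurons, the touch-sensing neurons of head and trunk, made up 11.2% at 14 h (10.1 to 12.4), 6.43% at 18 h (5.97 to 6.91) and 5.23% at 22 h (4.38 to 6.18). At 48 h, lateral-line or statoacoustic-like neurons made up 9.19% (8.31 to 10.1) and epibranchial-like neurons 7.65% (6.84 to 8.52). Neither class was named at 14, 18 or 22 h, and no trigeminal or Rohon-Beard-like cluster at 48 h. The marker list did not divide lateral line from statoacoustic neurons, so lateral-line-like stands for both below. The shares of these classes moved with the clustering. The trigeminal or Rohon-Beard-like share was 12.8% at 14 h and 11.6% at 22 h with resolution 0.6, 3.31% at 14 h with resolution 1.6, and 10.5% at 22 h with at least 1000 genes per cell, and 4.17% at 18 h with the automatic doublet threshold. With resolution 1.6, at least 1000 genes and list genes in the clustering, the lateral-line-like share was 4.06%, 4.67% and 3.66%, and with the first of these settings and at least 1000 genes the epibranchial-like share was 4.06% and 5.05%.

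Photoreceptor-like cells made up 0.663% of the cells at 18 h (0.518 to 0.836), 1.35% at 22 h (0.929 to 1.89) and 15.9% at 48 h (14.8 to 17.1). In them the receptor gene ret stood at 41.2, 127 and 5.97 CPM at 18, 22 and 48 h. The shared name is thus not shown to hold the same cell type at each age. Olfactory neuron-like cells made up 6.66% at 22 h (5.70 to 7.72) and 10.3% at 48 h (9.39 to 11.3). Pancreatic endocrine-like cells were present at every age, with 3.25%, 3.47%, 5.23% and 1.26% at 14, 18, 22 and 48 h. Motor neuron-like cells made up 4.90% at 14 h and 2.62% at 18 h. Hatching gland-like cells made up 13.0% at 14 h, and epidermis-like cells 6.85%, 4.50%, 7.80% and 1.49% at 14, 18, 22 and 48 h. Neural progenitor-like cells made up 4.81% at 18 h, 8.57% at 22 h and 9.67% at 48 h. Hindbrain or spinal interneuron-like cells made up 9.91% at 18 h and 2.69% at 22 h. Forebrain excitatory neuron-like cells made up 4.22% at 14 h, 8.53% at 18 h and 0.757% at 48 h. The sort and the rules of naming set these shares, and 32.1%, 41.2%, 58.1% and 31.2% of the cells stayed unnamed. The requirement for hmx2 or hmx3a, set after seeing the data, kept 1 cluster with 3.89% of the 18 h cells out of the lateral-line-like class, and none at the other ages. This cluster, number 9, shared 14 of its 25 leading genes with trigeminal or Rohon-Beard-like cluster 6 of 14 h, while the 18 h cluster of that class, number 3, shared 6 with cluster 7 of 14 h. At 22 h, unnamed cluster 16, with 2.45% of the cells, shared 8 with cluster 6. Unnamed 22 h cluster 7, with 6.41% of the cells, shared 9 with cluster 7 of 14 h. It was not added below because its UMI count was low, and adding it would raise the 22 h share further. With clusters 9 and 16 added to the class, a choice made after seeing the data, its share was 10.3% at 18 h and 7.68% at 22 h, so the limits of this class at the later ages are open. Leading genes set against a name kept out 4.86% of the 22 h cells and none elsewhere.

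**Figure D1:**
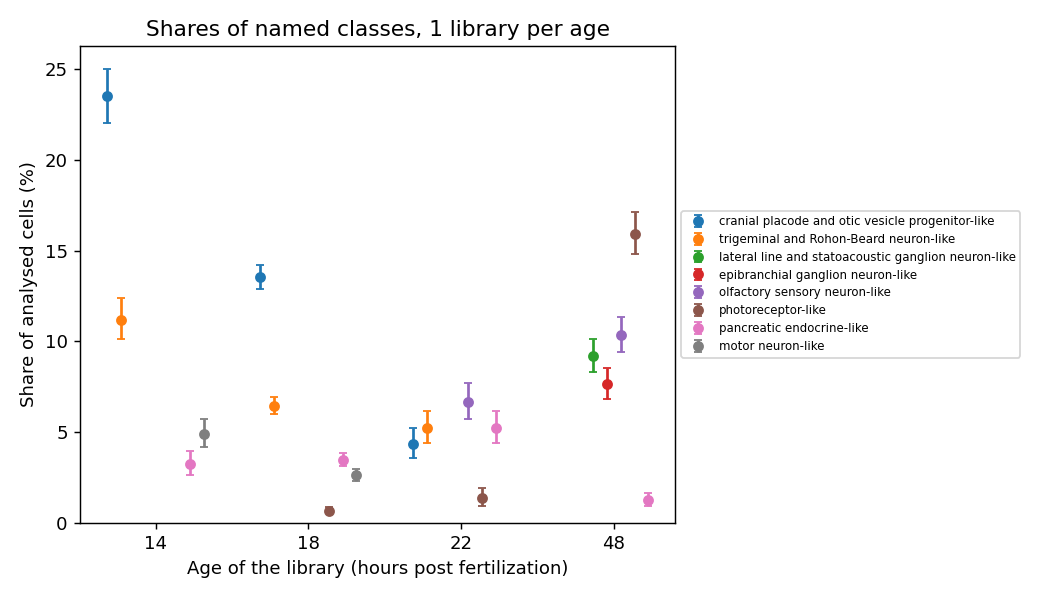
Share of analysed cells (%) in 8 named classes against the age of the library in hours post fertilization, with points for libraries and bars for exact 95% intervals of counting error. Placode-like cells stand at 23.5% at 14 h, and photoreceptor-like cells at 15.9% at 48 h.

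The series title concerns pioneer neurons and retinoic acid, and ret, the receptor of GDNF-family ligands, was used to divide sensory neurons. In the 48 h lateral-line-like neurons (cluster 2), ret stood at 120.3 CPM (109 to 132), and in the epibranchial-like neurons (cluster 3) at 98.0 CPM (88.2 to 108). Of the 364 lateral-line-like cells, 32.4% had a ret UMI (27.6 to 37.5) at a median of 10378.5 UMIs. In epidermis-like cells of that library, which should lack the gene, the share was 11.9% (4.91 to 22.9) at a median of 11016 UMIs. Thinned to 2000 UMIs, the shares were 19.4% (14.9 to 24.4) of 284 lateral-line-like cells and 1.96% (0.0496 to 10.4) of 51 epidermis-like cells, with 80 and 8 shallower cells left out. Muscle-like cells of that library had a ret UMI in 12.2% (7.15 to 19.1) at a median of 4055 UMIs, and ret at 40.7 CPM (29.6 to 54.6). Thinned, their share was 7.23% (2.70 to 15) of 83 cells, with 48 left out, and this interval overlaps that of the lateral-line-like cells. In the larger photoreceptor-like (631 cells) and olfactory neuron-like (409 cells) classes of that library the shares were 2.38% and 5.62%. Thinned, they were 1.05% (0.343 to 2.44) and 2.33% (0.943 to 4.75). Epibranchial-like cells had 35.3%, and 15.6% (11.3 to 20.8) thinned. The thinned lateral-line-like share was 39.5% at resolution 1.6 and 39.8% with at least 1000 genes per cell.

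Among the trigeminal or Rohon-Beard-like neurons, ret stood at 61.2 CPM at 14 h (clusters 6 and 7), 40.3 at 18 h (cluster 3) and 93.7 at 22 h (cluster 9). Pancreatic endocrine-like cells held 234, 122, 441 and 127 CPM at 14, 18, 22 and 48 h, and motor neuron-like cells 198 and 139 CPM at 14 and 18 h. In epidermis-like cells ret stood at 5.34, 7.85, 7.66 and 23.8 CPM at the 4 ages.

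**Figure D2:**
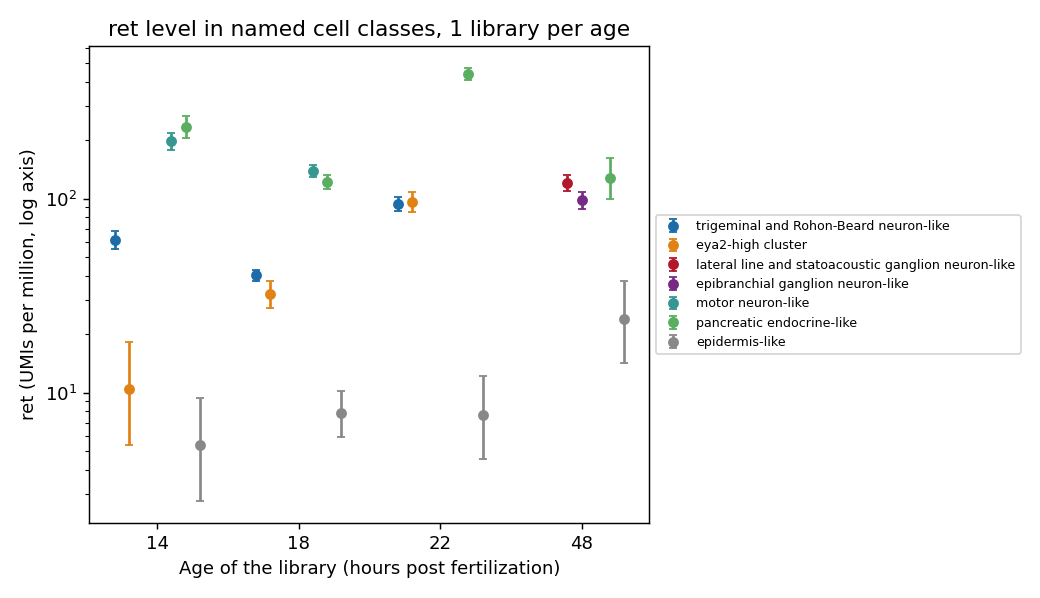
Level of ret in CPM (log axis) against the age of the library in hours post fertilization, with points for named classes in a library and bars for exact 95% Poisson intervals of counting error. Pancreatic endocrine-like cells at 22 h stand highest, at 441 CPM, and epidermis-like cells lie lowest of the plotted classes at each age, from 5.34 to 23.8 CPM.

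Cells with and without a ret UMI were then compared over the sensory-like clusters of all 4 libraries. The co-receptor gene gfra1b was higher in ret-positive cells, with a log2 fold change of 1.43 ± 0.21 (SE, edgeR adjusted p = 0.0134), and was higher in 4 of 4 libraries. Hox genes also rose: hoxd9a by 1.32 ± 0.16, hoxc8a by 1.26 ± 0.16, hoxb9a by 1.1 ± 0.17 and hoxb6b by 0.95 ± 0.15, each in 4 of 4 libraries. At 48 h the direction rests on little: hoxd9a had 13 against 11 UMIs, hoxb6b 32 against 26 and hoxb9a 83 against 86 (27.5 against 21.2 CPM). There hoxc8a had 22 against 8 UMIs. At 22 h hoxb6b had 5 UMIs in ret-negative cells. The median log2 ratio of the Hox list was 1.08 at 14 h, 0.79 at 18 h and 0.64 at 22 h, but -0.019 at 48 h, where 12 of 26 genes lay above 0. It was 0.11 at 22 h (0.0082 to 0.47) with cells matched by depth and -0.046 at 14 h with cells matched by cluster and depth, against 0.54 at 18 h matched by depth. With thinned cells the value of hoxb9a was -0.038. Of 12764 genes tested with edgeR, 17 were higher and 4 lower in ret-positive cells, ret left out. Without the 14, 18, 22 or 48 h library, 4, 1, 1 and 78 genes were higher and 0, 0, 0 and 37 lower, with 487, 635, 840 and 884 at an unadjusted p under 0.05 (DESeq2 on all 4 libraries, 19 and 5). The call of gfra1b ended without the 18 h library (1.35, edgeR adjusted p = 0.127) and without the 22 h library (1.35, adjusted p = 0.106). With the 18 and 22 h look-alike clusters 9 and 16 added to the pool, edgeR called 4 genes higher and 0 lower (635 at an unadjusted p under 0.05). These were gfra1b (1.22, adjusted p = 0.0423), slc18a3a (2.54), slc5a7a (3.5) and mnx1 (2.99). Of 31 Hox genes, 0 were then called in edgeR (13 at an unadjusted p under 0.05), the list median went from 0.76 to 0.41 and hoxd9a stood at 0.54. Ret-positive cells were much deeper, with median UMIs of 22674 against 7169 at 14 h, 44123 against 16529 at 18 h, 56744 against 4286 at 22 h and 12726 against 9136 at 48 h. With the automatic doublet threshold, the 18 h arms went from 308 and 380 cells to 125 ret-positive and 255 ret-negative cells. Their median UMIs were then 28475 and 12946. Of the 21 called genes, 20 could be tested under that threshold and 13 were called again. Whether remaining doublets contribute to these differences was not tested.

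The other genes named by the rule were mybpc1 (2.84 ± 0.43), the myosin light chain gene myl9a (1.2 ± 0.15), stm (1.04 ± 0.18) and the mitotic gene cenpf (0.99 ± 0.17), all higher. At 48 h mybpc1 and myl9a each had 2 against 0 UMIs and stm had 1 against 1, too few for a direction in that library. The value of cenpf turned to -0.036 with cells matched by cluster and depth, to -0.021 matched by depth alone and to -0.60 in the eya2-high clusters compared within libraries, where myl9a stood at -0.30. Lower were the synaptic adhesion gene lrfn4a (-1.14 ± 0.16), the calcium channel subunit cacna2d2a (-1.11 ± 0.16) and wscd2 (-0.89 ± 0.15). The value of cacna2d2a turned to 0.10 with thinned cells and to 0.080 in the eya2-high clusters. Called outside the rule were genes of acetylcholine use: slc5a7a (3.98 ± 0.53), chata (3.49 ± 0.52) and slc18a3a (3.05 ± 0.26), each higher in CPM at 14, 18 and 48 h. At 18 h they had 245 against 5, 136 against 7 and 535 against 32 UMIs. Counts were far lower at 14 h (10 against 3, 4 against 0 and 40 against 6) and 48 h (6 against 0, 13 against 1 and 8 against 1). At these 2 ages the counting intervals of the arms part only for slc18a3a at 14 h and chata at 48 h. The 22 h library held 1, 0 and 3 UMIs of them, too few for a direction. The motor neuron gene mnx1 (2.79 ± 0.35) had 0 UMIs at 48 h, and prox2 (3.25 ± 0.46) was seen in 2 libraries, with 142 against 20 UMIs at 48 h. The gene sp5l (1.07 ± 0.14) was higher at 14, 18 and 22 h, with 2 against 3 UMIs at 48 h. The low value of gch2 (-4.16 ± 0.71) rests on 18 against 330 UMIs at 18 h. For slc18a3a, 535 of the UMIs came from ret-positive cells of the 18 h library. RNA or cells of motor neurons were not excluded as a source of these acetylcholine genes. Of the 21 called genes, 4, 0, 1 and 19 were called again without the 14, 18, 22 and 48 h library.

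Of 31 Hox genes tested, 4 were higher over all genes (6 in DESeq2) and 21 were higher when adjusted over the list alone. Of 14 Ret and neurotrophin genes, gfra1b passed over all genes, and 2 were higher adjusted over the list alone. Its relative gfra3 had a log2 fold change of 1.06 ± 0.26, with edgeR adjusted p = 0.192. Of 31 cell cycle genes, 0 passed in edgeR or DESeq2 over all genes, with 12 at an unadjusted edgeR p under 0.05, and 6 were higher adjusted over the list alone. Of 74 axon guidance genes, 0 passed in edgeR or DESeq2 over all genes, with 20 at an unadjusted edgeR p under 0.05. Adjusted over the list alone, 5 were higher and 6 lower. The other lists also had 0 genes past either tool over all genes. Unadjusted edgeR p under 0.05 were found for 3 of 18 FGF, 8 of 39 axon growth, 7 of 37 synapse, 2 of 31 ion channel, 7 of 41 proneural, 2 of 24 Notch, 0 of 24 heat shock and 3 of 9 neuropeptide genes. Adjusted over the list alone, 1 synapse and 2 proneural genes were lower and 0 of the others passed.

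Of the 18 testable retinoic acid genes, 0 passed with edgeR, over all genes or adjusted over the list alone, and 0 with DESeq2, while 2 had an unadjusted edgeR p under 0.05. These were the retinoic acid degrading enzyme gene cyp26c1 (1.49 ± 0.46, adjusted p = 0.385) and the binding protein gene crabp2b (0.92 ± 0.36, adjusted p = 0.657). Among the others, the values were -0.15 ± 0.20 for cyp26b1, -0.35 ± 0.42 for the synthesis enzyme gene aldh1a2, 0.70 ± 0.42 for dhrs3b, 0.92 ± 0.68 for stra6, -0.45 ± 0.26 for rdh10a and -0.86 ± 0.52 for rdh10b. For the binding proteins they were 0.11 ± 0.13 for crabp1b and -0.81 ± 0.38 for crabp2a. For the receptors they were 0.22 ± 0.25 for raraa, 0.22 ± 0.19 for rarab, -0.15 ± 0.16 for rarga, -0.76 ± 0.53 for rxraa, -0.09 ± 0.12 for rxrba and -0.02 ± 0.19 for rxrbb. The corepressor gene ncor1 stood at 0.07 ± 0.12. With cells matched by depth, edgeR called 1 gene higher and 0 lower (730 at an unadjusted p under 0.05), and the log2 fold change of gfra1b was 1.37 with an adjusted p of 0.0925. Its edgeR call also ended at resolution 0.6 (1.05, adjusted p = 0.140) and with at least 1000 genes per cell (1.0, adjusted p = 0.498).

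The next question was how lateral-line-like neurons, which were not divided from statoacoustic neurons, differ from trigeminal or Rohon-Beard-like neurons. No library held both classes, so 48 h lateral-line-like cells were set against 22 h trigeminal or Rohon-Beard-like cells without a test, and class cannot be separated from age. The retinoic acid degrading enzyme gene cyp26b1 was 20.7-fold higher in the lateral-line-like cells (16.3 to 26.8), at 246 against 11.8 CPM. The co-receptor gene gfra1b was 11.4-fold higher (9.25 to 14.1), and its relative gfra1a 138-fold (37.5 to 1146), with 2 UMIs in the 22 h cells. The binding protein gene crabp1b stood at 74.9 against 641 CPM and the growth factor gene bdnf at 18 against 58.9 CPM.

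Other list genes higher in the lateral-line-like cells were the ephrin receptor gene epha4b (22.4-fold, 17.9 to 28.3), efnb3b (14.5-fold, 11.6 to 18.4), plxna1a (17.8-fold, 12.8 to 25.4) and cdh4 (19.8-fold, 14.1 to 28.5). Genes with few counts in the 22 h cells were plxna2 (78.9-fold, 33.3 to 245), plxnb2b (64.0-fold, 24.5 to 238), unc5db (142-fold, 38.9 to 1186), unc5da (46.7-fold, 12.4 to 395), crabp2a (46.7-fold, 17.8 to 174) and aldh1a2 (88.5-fold, 15 to 3559.9). Lower were the chemokine receptor gene cxcr4b (9.53 against 627 CPM), alcamb (141 against 1389 CPM), unc5b (6.26 against 95.9 CPM), etv4 (40.6 against 256 CPM), efnb1 (96.6 against 288 CPM) and flrt3 (43.6 against 129 CPM). Under other clusterings and class limits the cyp26b1 ratio ranged from 3.96 to 27.3 and the gfra1b ratio up to 23.9.

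A comparison within libraries was added after seeing the data. At 14, 18 and 22 h the cluster with the highest eya2 level, a placode-like cluster of 93, 342 and 106 cells, was compared with the trigeminal or Rohon-Beard-like cells of the same library. At 48 h eya2 was higher in neural progenitor-like (168 CPM) and epibranchial-like cells (109.6 CPM) than in the lateral-line-like cluster (55.8 CPM), so these clusters are not shown to be of that lineage. The 14, 18 and 22 h clusters were named from markers of placode and otic vesicle progenitors. The contrast thus sets progenitor-like cells against neurons, and class cannot be separated from maturity in it. Of 116 list genes tested with edgeR, ret left out, 14 were higher and 19 lower (21 and 24 in DESeq2). Without the 18 h library, edgeR called 1 list gene higher and 4 lower, and without the 22 h library 2 and 4. With the look-alike clusters counted as trigeminal or Rohon-Beard-like it called 17 and 18. The receptor gene gfra1a was higher by 3.93 ± 0.43 (edgeR adjusted p = 0.00895), and unc5db by 4.35 ± 0.68, slit1b by 3.96 ± 0.70 with 0 UMIs in the eya2-high cells at 14 h, plxna1a by 3.04 ± 0.56, efna5a by 2.38 ± 0.18 and fgfr4 by 1.81 ± 0.34. The retinoic acid receptor gene raraa was lower by -2.25 ± 0.29 (edgeR adjusted p = 0.0123). Also lower were plxna4 (-5.41 ± 0.37), etv4 (-4.49 ± 0.25), alcamb (-3.32 ± 0.28), bdnf (-3.30 ± 0.35), gfra3 (-3.27 ± 0.67), cxcr4b (-3.07 ± 0.23) and l1cama (-2.66 ± 0.26), each in 3 of 3 libraries. Of 13 Ret and neurotrophin genes, ret included, 1 was higher and 3 lower over all genes, and 2 and 5 when adjusted over the list alone. Of 69 axon guidance genes, 10 were higher and 10 lower over all genes, and 17 and 16 adjusted over the list alone. Of 18 FGF genes, 3 were higher and 5 lower by both adjustments. Other lists moved with this contrast, but their genes were not left out of the clustering that formed the groups. The proneural list also holds eya2, which picked the clusters. The ion channel list holds p2rx3a and p2rx3b, markers of the trigeminal or Rohon-Beard-like class. Calls in these lists in part follow from how the groups were formed and are no separate result. Of 35 synapse genes 1 was higher and 26 lower (1 and 29 adjusted over the list alone, median -2.18), of 38 axon growth genes 1 and 21 (1 and 31, median -1.39), of 21 ion channel genes 1 and 10 (1 and 13, median -2.28) and of 31 Hox genes 5 and 16 (7 and 20, median -3.17). Of 40 proneural genes 12 were higher and 8 lower (16 and 12 over the list alone). Of 26 Notch genes 3 were higher and 0 lower in edgeR (11 at an unadjusted p under 0.05; 10 and 1 in DESeq2; 8 and 1 adjusted over the list alone). Of 24 heat shock genes 7 were higher and 0 lower in edgeR (14 at an unadjusted p under 0.05; 9 and 0 in DESeq2; 11 and 2 adjusted over the list alone). Of 31 cell cycle genes 0 were higher and 2 lower in edgeR (7 at an unadjusted p under 0.05; 0 and 4 in DESeq2; 0 and 2 adjusted over the list alone), and of 6 neuropeptide genes 0 and 5 (5 at an unadjusted p under 0.05; 0 and 5 in DESeq2 and adjusted over the list alone). Of 17 retinoic acid genes, edgeR called 0 higher and 1 lower, also adjusted over the list alone (5 at an unadjusted p under 0.05; 2 higher and 2 lower in DESeq2). The value of cyp26b1 was 2.76 ± 0.85, which missed the threshold (edgeR adjusted p = 0.0995), with 0.54, 2.56 and 5.04 at 14, 18 and 22 h. That of gfra1b was 2.23 ± 1.18 (edgeR adjusted p = 0.269), with -3.41, 2.99 and 3.95 at these ages (1 against 74 UMIs at 14 h).

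The last question was how sensory-like neurons differ between ages. From 14 to 22 h both libraries held trigeminal or Rohon-Beard-like cells only (345 and 128 cells, in clusters 6 and 7 at 14 h and cluster 9 at 22 h). Ion channel genes stood higher at 22 h, with a list median log2 ratio of 1.97 over 22 genes, above 100% of random lists. Synapse genes (1.12 over 38 genes) and axon growth genes (0.95 over 40 genes) stood as far out. Neuropeptide genes had a median of 3.31 over 8 genes and cell cycle genes one of 0.54 over 32 genes, which was 1.37 at resolution 1.6 and -0.38 by the mean of per-cell CPM. Notch genes stood lower, with a median of -1.80 over 24 genes, and 0% of random lists had a lower median, but one of -0.48 at resolution 1.6. The medians were -0.62 for heat shock (23 genes), -0.41 for proneural (42), -0.32 for axon guidance (66), -0.24 for FGF (16), 0.11 for Hox (30, with 3.66 at resolution 1.6 and -0.35 with at least 1000 genes) and 0.61 for Ret and neurotrophin genes (11). Retinoic acid genes stood at 0.00062 over 12 genes, above 64.0% of random lists. From 14 to 18 h in cells given the same class name (cluster 3 at 18 h) they stood at 0.79 over 20 genes, above 100% of random lists, and from 18 to 22 h at -1.11 over 20 genes, above 0.05% of them. From 18 to 22 h Notch (-2.13 over 25 genes), cell cycle (-1.67 over 31 genes) and proneural genes (-0.78 over 42 genes) also stood low, above 0% of random lists. From 14 to 18 h cell cycle genes (1.90 over 31 genes) and Notch genes (0.91 over 26 genes) also stood above 100% of random lists. The 18 h library has another prefix in its name, another Cell Ranger release and another gene table, so these steps cannot be separated from the library. Cluster 3 also held a median of 26462.5 UMIs, against 12660 over the 18 h library. With the automatic doublet threshold, the sensory-like cells of 18 h went from 308 ret-positive and 380 ret-negative cells to 125 and 255. Whether doublets or mixed cells contribute to the 18 h steps was not tested. With the look-alike clusters added, the retinoic acid median was 0.65 from 14 to 18 h, above 99.9% of random lists, -0.50 from 18 to 22 h, above 2.49%, and -0.040 from 14 to 22 h, and the proneural median from 18 to 22 h was -0.23, above 9.12%. From 14 to 22 h the medians were then -1.14 for Notch, 0.30 for cell cycle, -0.13 for axon guidance and 0.20 for Hox genes. Single genes were not compared again with these clusters.

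Single genes higher at 22 h were the neurotrophin receptor gene ntrk3a (51.2-fold, 34.3 to 80.2), the potassium channel gene kcnc4 (59.2-fold, 35.1 to 109), pmp22b (112-fold, 54.3 to 280), dgkh (55.2-fold, 32.7 to 101) and syt9b (68.7-fold, 29.2 to 213). Also higher were p2ry1 (87.2-fold, 33.8 to 322), kcna1a (188-fold, 33.4 to 7461), scin (195-fold, 34.7 to 7747) and pnoca (172-fold, 30.5 to 6819). The gene nkl.2 was at least 46.7-fold higher. Lower were prdm1a (28.9-fold, from 29.4 to 1.01 CPM), prdm12b (32.5-fold, 10.7 to 160, with 3 UMIs at 22 h), gadd45ga (12.5-fold, from 63.2 to 5.07 CPM), prox1a (16.7-fold), vcana (43.1-fold, 11.6 to 363, with 2 UMIs at 22 h), nradd (28.5-fold), gngt2a (27.7-fold), sema3aa (18.4-fold) and rap1gap2a (10.4-fold). The peptide gene ccka was at least 63.8-fold lower. Among genes set apart, the keratin genes krt4 and cyt1 were 3.21-fold and 6.76-fold higher, and mt-nd5 stood at 158 against 233 CPM.

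From 22 to 48 h the comparison sets trigeminal or Rohon-Beard-like cells against lateral-line-like and epibranchial-like cells, so class and age change together. The genes that define these classes, such as phox2a, phox2bb, hmx3a and p2rx3a, lead the ranking and are no result. Other genes higher at 48 h were fabp7a (103-fold, 75.7 to 145) and shox (113-fold, 61.4 to 237), with pvalb5, sdk1b, col18a1b, erfl1 and sall3b at least 275-, 164-, 94.3-, 83.2- and 83.2-fold higher. Lower were the channel gene trpc4a (2836-fold, 509 to 112078), stm (1398-fold, 387 to 11551) and myl9a (320.5-fold, 88.3 to 2653), with 1, 2 and 2 UMIs at 48 h, and kitb (206 to 1.34 CPM), akap12a (217 to 1.61 CPM), itpr3 (134 to 0.536 CPM) and myl4 (131 to 0.536 CPM). The genes tagln2 and sema4aa were at least 224- and 178-fold lower. Among genes set apart, hbae3 was 15-fold higher (6.30 to 47.9) and epcam stood at 3.75 against 49.5 CPM.

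Retinoic acid genes had a median log2 ratio of 1.55 over 18 genes at 48 h against 22 h, above 100% of random lists, and one of 1.01 with look-alike cluster 16 added at 22 h. Its highest members were aldh1a2 (113-fold, 20 to 4508) and crabp2a (24.0-fold, 9.13 to 89.4), while crabp1b stood at 56.7 against 641 CPM and crabp2b at 1.74 against 23.0 CPM. Notch genes stood at 2.17 over 27 genes (0.60 at resolution 1.6 and 0.44 with at least 1000 genes), with her4.2 23.9-fold (18.9 to 30.7) and dlc 26.7-fold (12.8 to 67.2) higher. Axon guidance genes stood at 0.92 over 77 genes, with epha4l 79.1-fold (30.6 to 292) higher. Proneural genes stood at 1.24 over 42 genes (0.57 and 0.53 under these settings), with six1b 27.9-fold (23.7 to 33.1) higher. Hox genes stood at -2.23 over 31 genes, with hoxc9a at 2.01 against 183 CPM and hoxa5a 13.1-fold (5.80 to 36.5) higher. Ion channel genes stood at -1.0 over 31 genes, with scn1laa at 18.4 against 213 CPM, and synapse genes at -0.83 over 40 genes (-0.49 and -0.56 under these settings), with syn1 at 19.2 against 168 CPM. Stress genes of dissociation stood at 1.12 over 22 genes, although hsp90aa1.2 was lower, at 68.2 against 4278 CPM. The other medians were 0.42 for Ret and neurotrophin (15 genes), 0.45 for FGF (16), -0.61 for axon growth (41) and -0.43 for neuropeptide genes (11, with -0.10 when cluster 16 was added). The cell cycle median, 0.78 over 33 genes, turned to -1.24 at resolution 1.6 and to -1.20 with at least 1000 genes.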

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

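No paired analysis was possible between ages because each age has 1 library, while the ret and eya2-high contrasts compare arms within each library. Each result below is set against the value in the report. The cause of a change was not tested unless given. Counts of genes higher and lower in ret-positive cells were 123 and 84 without the low-count filter, 0 and 0 without the library block (edgeR, 16 genes at an unadjusted p under 0.05), 1 and 0 with at least 1000 genes (edgeR, 827 at an unadjusted p under 0.05), 1 and 2 at resolution 1.6, 1 and 0 with depth-matched cells (edgeR, 730) and 4 and 1 with thinned cells, where fewer genes were tested. Lower genes numbered 7 at resolution 0.6 and 1 with at least 2 ret UMIs. Chosen after seeing the data, matching by cluster and depth gave 4 higher, the eya2-high clusters gave 10 lower, and the look-alike clusters added gave 4 and 0 (edgeR, 635 at an unadjusted p under 0.05), with 4 of the 21 genes called again. Leaving out 1 library gave 1 to 78 higher and 0 to 37 lower, the highest without the 48 h library, where 19 of the 21 genes were called again. DESeq2 gave 19 and 5, with 16 of the 21 shared. Among single genes, cenpf turned to -0.036 and -0.021 with matching by cluster and depth and by depth alone, and to -0.60 in the eya2-high clusters, where myl9a stood at -0.30 and cacna2d2a at 0.080. With thinned cells hoxb9a stood at -0.038 and cacna2d2a at 0.10. The fold change of gfra1b stayed above 0 in the settings run, with adjusted p from 5.67e-10 (edgeR, no low-count filter) to 0.999941 (edgeR, no library block).

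For the class comparison, the cyp26b1 ratio was 7.02 at resolution 0.6, 11.8 at 1.6, 3.96 with at least 1000 genes and 11.4 with list genes in the clustering, and the gfra1b ratio was 19.8, 18 and 23.9 under the last 3. With look-alike clusters added they were 27.3 and 14.1. The planned count tests of that comparison were not run, since no library held both classes. On the eya2-high clusters, chosen after seeing the data, they gave 0 higher and 0 lower list genes without the library block (edgeR, 31 at an unadjusted p under 0.05; DESeq2 with the block, 21 and 24) and 33 lower without the low-count filter. Leaving out 1 library gave 1 to 16 higher and 4 to 19 lower.

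Shares of lateral-line-like cells were 4.06%, 4.67% and 3.66% at resolution 1.6, with at least 1000 genes and with list genes, and of epibranchial-like cells 4.06% and 5.05% under the first 2. Trigeminal or Rohon-Beard-like cells at 14 h made up 12.8%, 3.31%, 12.9% and 9.35% at resolution 0.6, 1.6, with at least 1000 genes and with list genes. At 22 h they made up 11.6% at resolution 0.6 and 10.5% with at least 1000 genes, and at 18 h 5.17% with doublets kept and 4.17% with the automatic threshold. With look-alike clusters added they made up 10.3% at 18 h and 7.68% at 22 h. The thinned share with a ret UMI was 39.5% at resolution 1.6, 39.8% with at least 1000 genes and 32.4% without thinning. For 22 h against 14 h, the Notch median was -0.48 at resolution 1.6, and that of the cell cycle 1.37 there and -0.38 by the mean of per-cell CPM. For 48 h against 22 h, resolution 1.6 and at least 1000 genes gave 0.60 and 0.44 for Notch, 0.57 and 0.53 for proneural, -0.49 and -0.56 for synapse and -1.24 and -1.20 for cell cycle genes, which stood at 0.41 by per-cell CPM.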

Other observations

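Within the eya2-high clusters and the 48 h lateral-line-like cluster, a comparison chosen after seeing the data, 10 of the 21 genes called in the pooled comparison could be tested, and 1 of them was called again. Higher in ret-positive cells were gfra1b (2.2 ± 0.20), the melanocortin accessory gene mrap2a (2.43 ± 0.28), the heat-gated channel gene trpv1 (2.40 ± 0.33), ptprdb (1.94 ± 0.22), chodl (1.70 ± 0.23), the microtubule regulator gene stmn3 (1.54 ± 0.17), ank2a (1.21 ± 0.14) and efnb1 (1.09 ± 0.17), each in 4 of 4 libraries except gfra1b and trpv1, which had 0 UMIs in ret-positive cells at 14 h. Lower were notch1a (-0.77 ± 0.12), rbpjb (-0.83 ± 0.14) and fstl1a (-1.60 ± 0.22). Over all genes edgeR called 15 higher and 10 lower. Of 38 axon growth genes, 0 passed over all genes (20 at an unadjusted p under 0.05), and 12 were higher and 2 lower adjusted over the list alone. Of 24 Notch genes, 1 was lower over all genes, and 1 was higher and 10 lower adjusted over the list alone. Of 7 neuropeptide genes, 0 were higher and 2 lower over all genes in edgeR, penkb (-3.28 ± 0.42, lower in 2 of 3 libraries with UMIs) and adcyap1a (-3.03 ± 0.43, lower in 2 of 2). Both calls rest on the 48 h library, with 28 against 494 and 17 against 234 UMIs in ret-positive and ret-negative cells. At 18 h the 2 genes had 0 against 1 and 0 against 2 UMIs, and penkb had 1 against 0 at 22 h. Adjusted over the list alone, 0 were higher and 3 lower (3 at an unadjusted p under 0.05, DESeq2 not run). The 14 h library had 10 ret-positive cells in this comparison.

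In the eya2-high clusters of 22 h against 14 h, ret stood at 96.6 against 10.4 CPM, cyp26b1 at 393 against 16.5 CPM and gfra1b at 278 against 0.868 CPM (319.96-fold, 57.3 to 12653, 1 UMI at 14 h), with no test. The axon growth gene stmn2b was 33.1-fold higher (19.3 to 62.4), and slit1b at least 23.7-fold. The Notch targets her4.1 and her6 were 27.0-fold and 38.7-fold lower, and the retinaldehyde reductase gene dhrs3b 85.0-fold (22.6 to 717, with 2 UMIs at 22 h). Synapse genes had a median log2 ratio of 2.24 over 32 genes and cell cycle genes one of -1.41 over 26 genes. The gene gfra3 stood highest of the named classes in motor neuron-like cells at 14 and 18 h, at 349.7 and 269 CPM.

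All tests below were chosen after the result was seen, except the Hox list under matching by cluster and depth, written when only the count of genes called again (3 of 18 testable) was known, and the median of endocrine markers. Ret-positive and ret-negative sensory-like sums differed in 20 genes with ret removed before fitting, and of the 35 splits of the 8 sums (32 fitted) 1 gave as many, but only 8 splits part the arms of every library, with 19 for the highest other, and these are too few for a share under 0.05. Splitting by 20 other genes found in a like share of cells gave as many genes in 5 of them, up to 208 for prdx5, which is consistent with depth as a source of the count. With cells matched by cluster and depth the median of the Hox list fell from 0.76 to 0.24, lower for 30 of 31 genes, which met the bound written for a mix of clusters, but the matching changes depth too and the ages differ, so the list as a whole, 0.41 with look-alike clusters added, stays open. At 14 h, with 2 clusters, the median was 0.88 matched by depth and -0.046 (-0.29 to 0.22) matched by cluster and depth, which goes with a mix of clusters at that age. At 18 h the cells were 1 cluster, so a mix of the clusters used here could not arise and was not tested. The median there was 0.54 (0.40 to 0.69) matched by depth, above 0 for 28 of 30 genes, so the list stood higher without such a mix. Differences within the cluster stay open. At 22 h, also 1 cluster, the median went from 0.64 to 0.11 (0.0082 to 0.47) matched by depth. At 48 h it was -0.017 matched by depth and -0.28 (-0.60 to -0.012) matched by cluster and depth, with 6 of 24 genes above 0.

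For gfra1b, the highest log2 fold change over the 20 other splits was 0.38, against 1.43 ± 0.21 in the split by ret, which argues against depth alone. With cells matched by cluster and depth it was 1.28 ± 0.35, which argues against a mix of clusters as the whole cause. The adjusted p there rose to 0.104 in edgeR with fewer cells and a wider spread, so the call ended. RNA of other cells was not tested for gfra1b and stays open. Shared expression of ret and its co-receptor gene in the same neurons remains a hypothesis, found and tested on the same data.

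For the acetylcholine genes, the 20 splits by other genes reached at most 0.599 of the log2 fold changes in the split by ret, which argues against depth alone, although they reached 1.82 (prdx5) and 1.37 (ubac1) for slc18a3a, 1.92 for chata and 2.03 for slc5a7a. Pancreatic endocrine-like cells at 18 h held at most 0.671 of the CPM of ret-positive cells, with slc18a3a at 25 (20.5 to 30.2) against 37.3 (34.2 to 40.6), which argues against such cells as carriers of slc18a3a, chata and slc5a7a there. The median over 4 pancreatic endocrine markers, 1.15, met the bound written for it, but it does not test the carriers, and ins was higher at 18 h (1074 against 47 UMIs), lower in CPM at 22 h (40 against 22), within counting error at 48 h (11 against 26) and too rare at 14 h (3 against 2), while gcgb stood at -1.48 ± 0.72. The 1 further testable motor neuron marker, lhx4, stood at 1.83, above 1, which is too few to decide, and at 14 h it held 1.70 CPM (0.463 to 4.35) in ret-positive and 398 in motor neuron-like cells, where slc18a3a held 17 and 402 CPM. At 18 h, 13 other genes specific to motor neuron-like cells implied a median of 3.94% motor neuron RNA in ret-positive cells (0.914 to 5.96). The share from slc18a3a was 4.66%. The median was 4.44% when ret was among the genes and 3.12% without lhx4 and gfra3. Of the 13 genes, 12 were higher in ret-positive cells, and uts2d implied -1.14%. Each median met the bound written for this source. The interval, required only after the values were seen, also reaches the bound against it. RNA or cells of motor neurons remain a possible source at 18 h, one that the medians go with, and are not settled there. They stay open at 14 and 48 h, and no biological explanation was tested.

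For the list genes between eya2-high clusters and trigeminal or Rohon-Beard-like cells, the real split of the 6 sums called 33 and the highest other split 0. The real split was the 1 of 10 splits with as many, and 10 splits are too few for a share under 0.05.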
